A study of Mus musculus with 6 samples.

How the data were processed

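The study applied RRBS to genomic DNA of E14 mouse embryonic stem cells. Per the labels' protocols, DNA was cut with MspI, made into Illumina TruSeq libraries, bisulfite converted with a Qiagen EpiTect kit and sequenced on a HiScanSQ. The submitters' processing notes name CASAVA 1.8, Bismark 0.10.1 and the mouse build mm9, without saying what each was used for. Positions on assembled chromosomes lay within the mm9 chromosome lengths. The coverage minimum, the treatment of duplicate reads and the adapter trimming are not given in the sources used here.

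Each of the 6 deposited files holds 1 library. The title of the Dnmt1 sample names its shRNA as Dnmt1a, while its treatment label names Dnmt1, and the treatment label was followed. Its values are methylation fractions from 0 to 1, rounded by the authors to 3 decimals, for single cytosines of CpG sites on 1 strand, with 5 bases of context. The files list between 445016 and 604227 cytosines, and 67 to 135 per library have no level and were left out. The fractions come without counts or coverage, so the depth behind a level is unknown. No counting interval can be given, and levels of thinly and deeply covered cytosines weigh alike. Fractions were multiplied into percent. Start positions were read as BED positions, and printed positions are 1-based.

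Before the data were examined, the groups, comparisons, thresholds and alternatives were fixed. The plan had a Fisher's exact test per cytosine, coverage minimums and pooled reads, which need counts and were not run. It also had promoters and lists of imprinted, germline, pluripotency, primed state, developmental, housekeeping, methylation machinery, trophoblast, 2-cell and tissue-restricted genes. These need gene positions on mm9. The gene table at hand is for another build and was not used for positions, so no gene is named and none of these lists has a result. The rule for items named in the text then fell to its second form: for each knockdown, up to 3 clusters with the largest fall and up to 3 with the largest gain among those past the thresholds. Such clusters are picked for extreme values, so their differences overstate what a repeat would show.

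Levels were joined by chromosome, position, strand and context with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6, and plotted with matplotlib 3.10.9. Mean differences used the 369208 autosomal cytosines listed in all 6 libraries, which are 50.4% of the 733073 listed in any. Single cytosines were compared wherever control and the knockdown both had a level, and called at a difference of at least 20 percentage points. Clusters joined cytosines listed in all 6 libraries that lay at most 100 bp apart. They had at least 5 cytosines and were called at a mean difference of at least 20 points with at least 80% of cytosines in that direction. Classes were set on the median over the 6 libraries, not on control, since a split on control alone would bring regression to the mean. A library that is lowered then takes part in setting the classes, so classes set on the Dnmt3b and the Tet1 and Tet2 libraries were tried as well, and on Dnmt3b alone for the Tet1 and Tet2 knockdown.

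With 1 library per group no test between conditions was possible. Other measures describe the spread. The SD over the 19 autosomes describes the genome. The plus and minus strands of a cluster come from different molecules of the same library and repeat the measurement, but not the culture. CpG sites with both strands listed gave the error of single cytosines: in control the strands differed by an SD of 17.7 points over 2353 intermediate CpGs and by 3.73 points over 8208 low ones.

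The cluster rule was tested on simulated libraries, with noise taken from the difference between the Dnmt3b and the Tet1 and Tet2 libraries. Of 200 clusters lowered by 25 points among 22524, 91.5% were recovered. The share was 6% for 15 points and 100% for 40 points, and 0 unchanged clusters were called in these runs. In simulated libraries without any change, 1 cluster was called, as higher for Dnmt3b. The simulation draws each cytosine independently, so it understates noise shared by cytosines on 1 read. The same noise gave the simulated correlation for the shared control.

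The alternatives were differences of 10 and 30 points, clusters of at least 3 or 10 cytosines, gaps of 50 or 300 bp, other sets of cytosines, a median level of at least 50%, sex chromosomes included, and the 2 strands of a CpG merged. Strand-wise values, clusters past 10 points on both strands, the other classes and the set without the Dnmt1 library were added after the data were seen. With 1 library per group none could be left out.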

Results

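DNA methylation was profiled by reduced representation bisulfite sequencing (RRBS) in 6 libraries of E14 mouse embryonic stem cells, 1 library per group. RRBS cuts genomic DNA at CCGG with MspI, which enriches CpG-rich sequence, and bisulfite turns unmethylated cytosines into uracil while 5-methylcytosine and 5-hydroxymethylcytosine are read as cytosine. The cells carried a control short hairpin RNA (shRNA) or shRNAs against Tet1 and Tet2 together, Dnmt1, Dnmt3a, Dnmt3b, or Dnmt3a and Dnmt3b together. TET1 and TET2 oxidise 5-methylcytosine, DNMT1 copies methylation onto newly replicated DNA, and DNMT3A and DNMT3B methylate DNA de novo. The libraries listed between 445016 cytosines (Dnmt1) and 604227 cytosines (Tet1 and Tet2), each the cytosine of a CpG on 1 strand. Control listed 588220, Dnmt3a 583020, Dnmt3b 573439 and the Dnmt3a and Dnmt3b double knockdown 554481. Read depth per cytosine is unknown, since only methylation levels were given. There were no replicates, so every difference below is between 2 libraries, has no replicate error and carries no p-value. The SD given with a mean is over the 19 autosomes and describes the spread along the genome only.

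Levels were compared over the 369208 autosomal cytosines listed in all 6 libraries. Control cells had a mean level of 25.7% ± 1.4 (SD over autosomes). Over each library's own autosomal cytosines, sets that differ between libraries, control read 32.30%. On such sets Tet1 and Tet2 read 32.27%, Dnmt3b 33.08%, Dnmt3a 28.48%, the double knockdown 27.96% and Dnmt1 5.16%. Cytosines were grouped by their median over the 6 libraries: 252414 were low (below 20%), 57525 intermediate and 59269 high (above 80%). Mitochondrial DNA served as the background. There, the 94 cytosines listed in all libraries averaged 0% in control and at most 0.066% in any knockdown (Dnmt1).

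The Dnmt1 knockdown asked how much of the methylation depends on the maintenance enzyme. It had the lowest methylation of the 6 libraries: the mean level was 5.38% ± 0.42, a difference from control of -20.3 ± 1.1 percentage points or -79.0% in relative terms, and it was lower on all 19 autosomes. High cytosines stood at 21.4% ± 0.8 against 90.2% ± 0.2 in control, and intermediate cytosines at 10.7% ± 0.4 against 64.0% ± 0.7. Low cytosines stood at 0.40% against 1.76%. Cytosines above 80% made up 0.128% of the set in this library and 18.8% in control.

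The loss after Dnmt1 knockdown was seen at nearly all methylated sequence. Of 409044 autosomal cytosines listed in both libraries, 127062 (31.1%) were lower by at least 20 points and 47 were higher. Neighbouring cytosines were also joined into 22524 clusters of at least 5 cytosines, with a median of 9 cytosines over 125 bp. In these, 5165 clusters were lower by at least 20 points with at least 80% of their cytosines in that direction, and 0 were higher. The lower clusters held 97.6% of all intermediate and high clusters. Among clusters with at least 3 cytosines on each strand, 1628 were lower by at least 20 points on the plus strand. Of these, 1626 were also lower on the minus strand, which is read from other molecules. Intermediate and high clusters differed from control by means of -49.1 and -66.6 points. Whether the recurrence goes beyond the general loss of these classes was not tested. The 3 clusters with the largest differences lay on chromosome 15 (99063177 to 99063282, mm9), chromosome 13 (73774665 to 73774769) and chromosome 7 (27999411 to 27999512). Their levels were 92.5%, 94.0% and 95.7% in control and 5.30%, 7.65% and 9.38% after Dnmt1 knockdown. The Dnmt1 library listed the fewest cytosines, and 34.1% of the high cytosines listed in the other 5 libraries were not listed in it, against 10.9% of the low ones. Over the cytosines shared with control alone, the mean difference was -19.8 points.

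**Figure D1:**
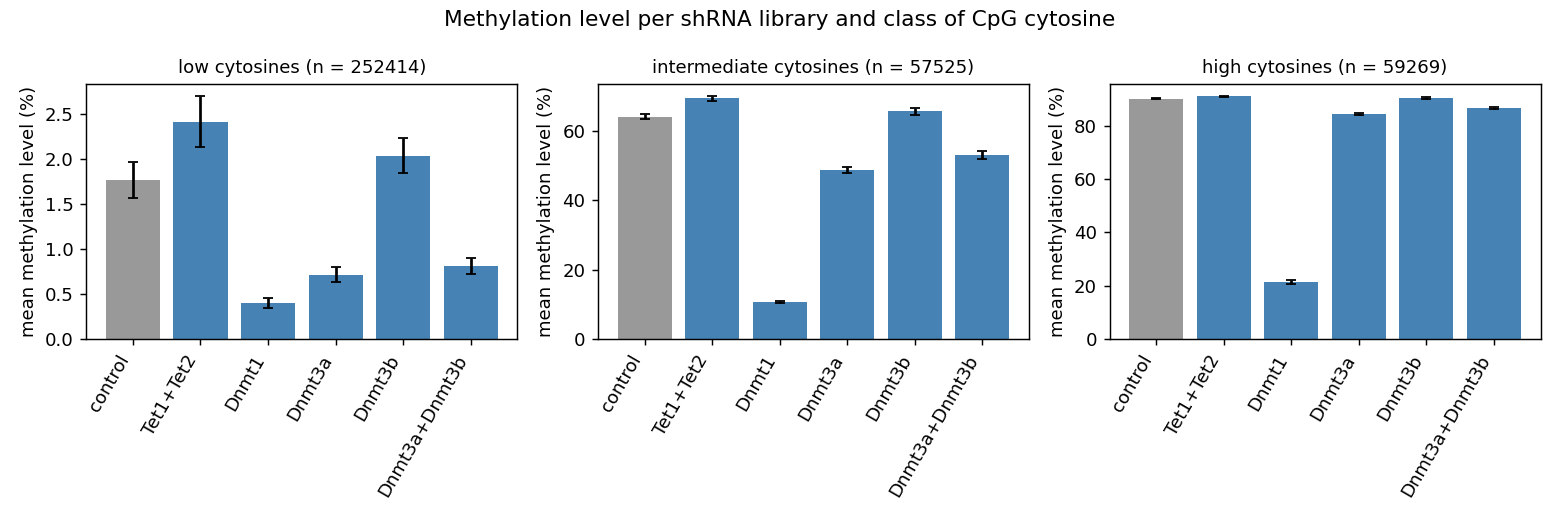
Mean methylation level (%, vertical axes from 0, different scales) of low, intermediate and high cytosines in each of the 6 shRNA libraries. Bars are means over the cytosines of the class and error bars the SD over 19 autosomes; the Dnmt1 bar stands at 21.4% for high cytosines against 90.2% in control, and the Tet1 and Tet2 bar is the highest in each class.

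The Dnmt3a knockdown, which asked what depends on that de novo enzyme, was lower than control mainly at intermediate cytosines. The mean over all cytosines was 21.6% ± 1.4, a difference of -4.02 ± 0.32 points, and was lower on all 19 autosomes. Intermediate cytosines differed by -15.3 ± 0.5 points (48.7% against 64.0%) and high cytosines by -5.71 ± 0.32 points. Low cytosines stood at 0.715% against 1.76% in control, which is 40.5% of the control level. At single cytosines, 41355 of 517316 (7.99%) were lower by at least 20 points and 1515 higher. At clusters, 756 were lower and 0 higher, and 730 of the 756 were intermediate clusters. The classes include the lowered libraries themselves, which moves some highly methylated sequence into the intermediate class. With classes set on the Dnmt3b and the Tet1 and Tet2 libraries instead, a choice made after the data were seen, 653 of the lower clusters were intermediate and 102 high, against 15 high before. Intermediate cytosines then differed by -15.3 points and high ones by -7.38 points. Of 316 clusters lower by at least 20 points on the plus strand, 310 were lower on the minus strand. Their median there was -17.2 points, and 114 passed 20 points. Most called clusters were intermediate, a class that differed by a mean of -15.6 points. Whether the recurrence goes beyond this general fall was not tested. Within intermediate clusters the change hardly varied with the density of listed cytosines: those of the sparsest quartile differed from control by -15.7 ± 6.6 points (SD over clusters) and those of the densest quartile by -15.4 ± 7.7 points. In low clusters the change went from -2.55 ± 3.89 points in the sparsest to -0.63 ± 2.04 points in the densest quartile, and in high clusters the quartiles ranged from -7.46 ± 5.22 to -4.70 ± 4.97 points. Cluster counts depended on the size required: 3165 were lower by at least 10 points and 85 by at least 30.

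Of the Dnmt3a clusters, the one with the largest difference lay on chromosome 8 (90304832 to 90304851, 5 minus-strand cytosines) and read 77.6% in control and 21.0% after Dnmt3a knockdown. Control was the highest of the 6 libraries there, the others reading from 16.7% to 58.7%. A cluster on chromosome 11 (85287918 to 85288020) read 72.5% in control, 28.2% after Dnmt3a knockdown, 71.4% after Dnmt3b knockdown and 56.0% in the double knockdown. Another on chromosome 11 (69235215 to 69235262) read 54.2% in control, 13.3% after Dnmt3a knockdown and 20% in the double knockdown.

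The Dnmt3b knockdown library, in contrast, had a mean level slightly above control. It read 26.1% ± 1.5, which is 0.446 ± 0.093 points higher, on all 19 autosomes. No transcript or protein level was used here for any target. A weak depletion of Dnmt3b can therefore not be told apart from a small effect of its loss. Intermediate cytosines were 1.47 ± 0.43 points higher and high cytosines 0.21 ± 0.13 points higher. Single cytosines went both ways: 6314 of 515661 were lower by at least 20 points and 8983 higher. Within the control library the 2 strands of intermediate CpGs differed by an SD of 17.7 points. A call of 20 points at a single cytosine can therefore be measurement error, in any knockdown. Among the clusters, 5 were lower and 18 higher. Of 9 clusters higher by at least 20 points on the plus strand, 6 were higher on the minus strand and 1 passed 20 points there. Most of these gains thus did not reach that size on the minus strand, which mostly reads other CpGs. Of 6 clusters lower by at least 20 points on the plus strand, 3 were lower on the minus strand, with a median there of 0.42 points and 0 past 20 points. None of these 6 recurred at that size on the minus strand, which mostly reads other CpGs. With both strands past 10 points, 10 clusters were lower and 40 higher. Of the 5 lower clusters, 2 were also lower in the double knockdown, where lists independent within each class would share 0.48. Both lists were made against the same control library. The lower clusters with the largest differences lay on chromosome 6 (28368561 to 28368661, 37.5% against 62.8% in control), chromosome 1 (104859649 to 104859682, 37.8% against 63.1%) and chromosome 5 (102329245 to 102329346, 70.2% against 92.6%). The other lower ones, outside the rule for named clusters and added after their values were seen, lay on chromosome 11 (118769201 to 118769304, 59.8% against 80.3%) and chromosome 5 (124799414 to 124799447, 23.0% against 43.4%). Those with the largest gains lay on chromosome 10 (28916873 to 28916920, 48.0% against 13.9%), chromosome 4 (139775658 to 139775791, 42.7% against 16.7%) and chromosome 17 (45959420 to 45959461, 55.3% against 29.3%).

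The double knockdown asked whether targeting both de novo enzymes goes beyond targeting either. Its mean level was 22.7% ± 1.4, a difference from control of -2.94 ± 0.30 points, and was lower on all 19 autosomes. Intermediate cytosines differed by -11.0 ± 0.7 points and high cytosines by -3.54 ± 0.26 points. There were 23943 cytosines lower and 2059 higher by at least 20 points among 488742, and 291 clusters lower and 1 higher. The 3 with the largest differences were the chromosome 6 cluster named for Dnmt3b (19.4% against 62.8% in control), a cluster on chromosome 3 (59413458 to 59413507, 56.7% against 92.0%) and a cluster on chromosome 4 (141171033 to 141171081, 54.5% against 89.7%). The cluster that was higher lay on chromosome 8 (83263425 to 83263455, 82.3% against 61.4%). Of 138 clusters lower by at least 20 points on the plus strand, 134 were lower on the minus strand. Their median there was -12.6 points and 32 passed 20 points, so most did not reach that size on the minus strand. Of the 291 lower clusters, 278 were intermediate, a class that differed by a mean of -11.1 points. Whether the recurrence goes beyond this general fall was not tested.

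Compared directly, the double knockdown was less depleted than the Dnmt3a knockdown alone. It was 1.08 ± 0.10 points above Dnmt3a over all cytosines, 4.27 ± 0.45 points above it at intermediate cytosines and 2.17 ± 0.20 points above it at high ones, on all 19 autosomes in each case. Against Dnmt3b alone it was lower, by -3.39 ± 0.28 points. The 2 single differences from control summed to -3.57 ± 0.36 points, and the double knockdown lay 0.63 ± 0.13 points above that sum. The excess over the sum was 2.81 ± 0.51 points at intermediate and 1.96 ± 0.18 points at high cytosines, and 2.55 points at cytosines with a median level of at least 50%. At low cytosines the order turned: the double knockdown differed from the sum by -0.172 ± 0.063 points. The lists of lower clusters overlapped. Among 5189 clusters with a mean over the 6 libraries of at least 20%, 743 were lower for Dnmt3a and 281 for the double, and 194 were lower in both, where lists independent within each class would share 69.3. Both lists were made against the same control library, which can by itself bring clusters into both.

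**Figure D2:**
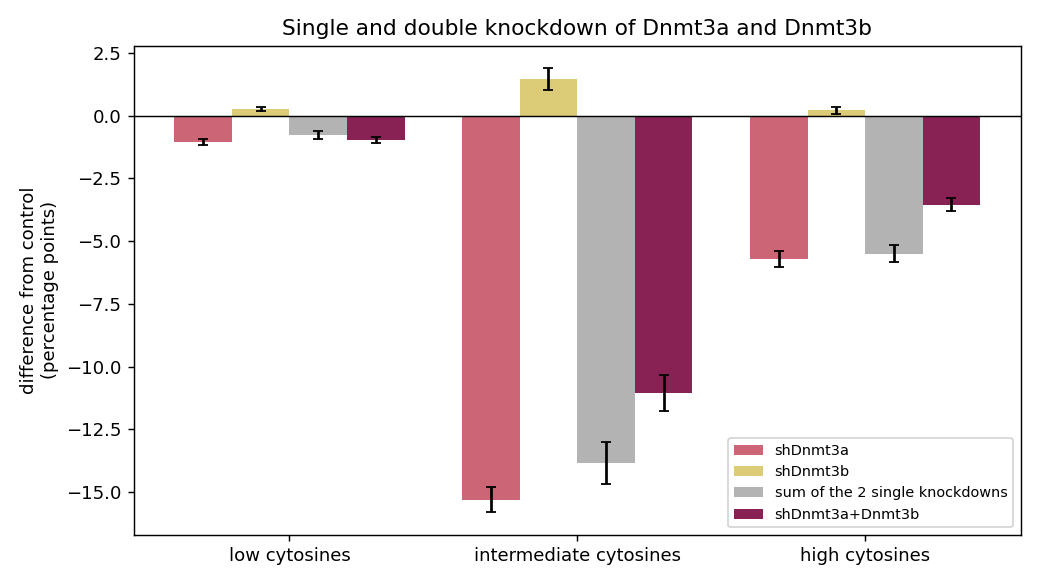
Difference from control (percentage points, vertical axis) at low, intermediate and high cytosines for the Dnmt3a, Dnmt3b and double knockdown libraries and for the sum of the single differences. Bars are means and error bars the SD over 19 autosomes; at intermediate cytosines the double stands at -11.0 points, above the Dnmt3a bar at -15.3 points.

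Knockdown of Tet1 and Tet2 together asked what happens when oxidation of 5-methylcytosine is reduced. Its library had the highest mean level over the cytosines listed in all 6 libraries. Over each library's own autosomal cytosines it read 32.27%, below control (32.30%) and Dnmt3b (33.08%). Over the shared cytosines its level was 27.1% ± 1.5, or 1.40 ± 0.16 points above control, on all 19 autosomes. The gain lay mainly at intermediate cytosines, which were 5.23 ± 0.38 points higher (69.2% against 64.0%), while high cytosines were 0.88 ± 0.12 points higher. With classes set on the Dnmt3b library alone, chosen after the data were seen, these gains were 5.61 and 1.49 points. Low cytosines read 2.41% against 1.76%, which is 137% of the control level. At single cytosines, 12987 of 503842 (2.58%) were higher by at least 20 points and 4477 lower. At clusters, 50 were higher and 4 lower. Of 31 clusters higher by at least 20 points on the plus strand, 27 were higher on the minus strand, with a median there of 9.16 points and 0 past 20 points. Across all 12251 clusters with at least 3 cytosines on each strand, 51.8% were higher on the minus strand, but 10637 of them were low. Of the 50 higher clusters, 40 were intermediate, a class whose clusters differed by a mean of 4.94 points. The 51.8% is therefore not a matched baseline for the 31 clusters. Whether their recurrence goes beyond the general gain of their class was not tested. Of 3 clusters lower by at least 20 points on the plus strand, 1 was lower on the minus strand, with a median there of 2.47 points. The largest gains lay on chromosome 4 (147455672 to 147455720, 61.7% against 13.7% in control), chromosome 7 (125577861 to 125577910, 98.0% against 61.7%) and chromosome 13 (6631171 to 6631268, 63.3% against 29.2%). The lower clusters included chromosome 2 (174125974 to 174126021, 27.2% against 57.4%), chromosome 12 (100883432 to 100883477, 27.7% against 57.9%) and the chromosome 8 cluster named for Dnmt3a (50.3% against 77.6%). The remaining lower cluster, added after its value was seen, lay on chromosome 8 (13795590 to 13795638, 72.0% against 92.9%). Most of the clusters named for Tet1 and Tet2 by the rule held cytosines of 1 strand only, so their values have no second-strand reading.

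**Figure D3:**
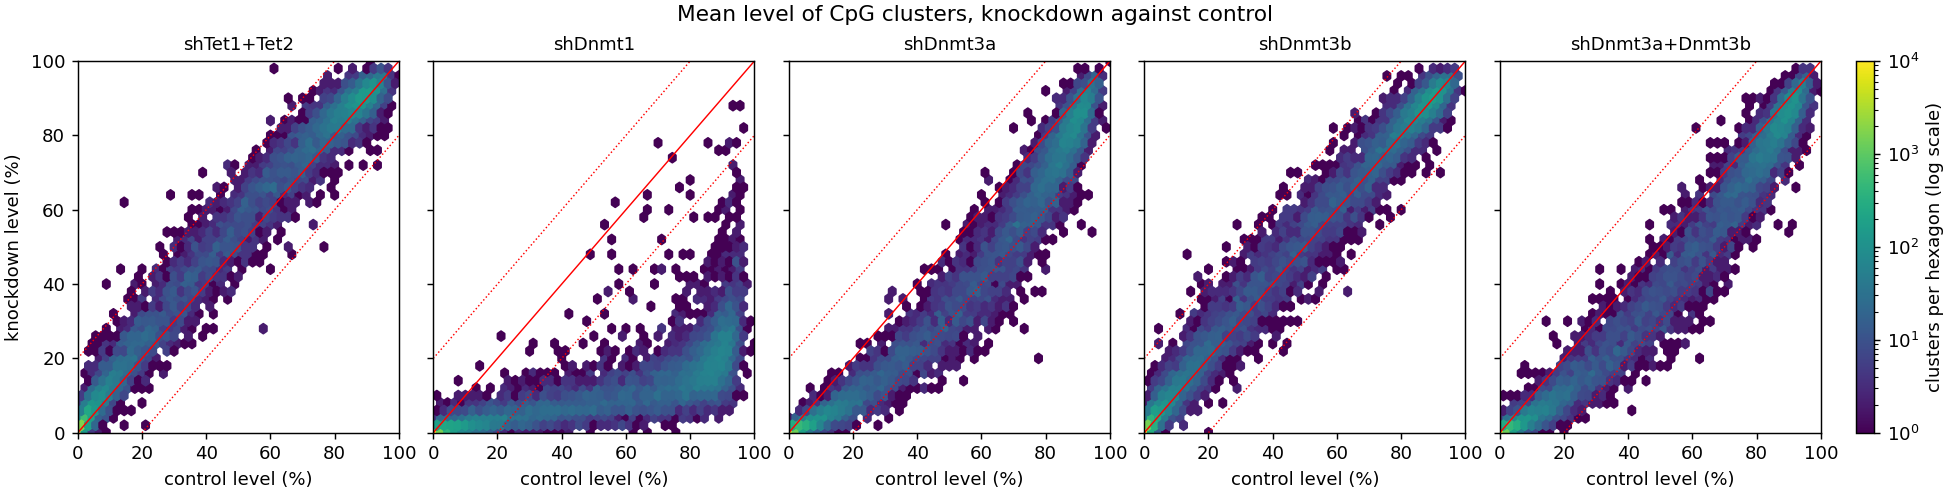
Mean level of each of 22524 CpG clusters in a knockdown library (%, vertical axis) against control (%, horizontal axis), 1 panel per knockdown; colour is the number of clusters per hexagon on a log scale, the solid line marks equal levels and the dotted lines differences of 20 points. Most methylated clusters lie far below the line for Dnmt1, intermediate ones lie below it for Dnmt3a and the double, and those of Dnmt3b spread around it.

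The 5 knockdown profiles were compared with each other across clusters. All differences share the control library, and libraries simulated without any change correlated at r = 0.50 across cytosines for that reason alone. Differences were therefore correlated between the plus strand of one knockdown and the minus strand of another, over 12251 clusters with at least 3 cytosines on each strand; clusters are not independent replicates. Dnmt3a and the double knockdown correlated at r = 0.68, Dnmt3a and Dnmt1 at 0.66, and Dnmt3a and the Tet1 and Tet2 knockdown at -0.43. Tet1 and Tet2 against Dnmt3b gave 0.16. These pooled values also carry differences between the classes, and 10637 of the 12251 clusters were low. Over all 22524 clusters, Dnmt3a differed from control by -1.08, -15.6 and -6.25 points in low, intermediate and high ones. For Dnmt1 these mean differences were -1.42, -49.1 and -66.6 points. Dnmt3a and Dnmt1 correlated at 0.68 within low, -0.063 within intermediate and 0.019 within high clusters. For Dnmt3a and the double the values were 0.66, 0.16 and 0.056, and for Dnmt3a and the Tet1 and Tet2 knockdown -0.41, -0.11 and -0.11. In low clusters a fall cannot exceed the level in control. Low cytosines read 1.76% in control, 0.40% for Dnmt1, 0.71% for Dnmt3a and 0.81% in the double. Differences in starting level within the low class were not separated, so 0.68 and 0.66 do not by themselves show shared sites of loss. Within intermediate and high clusters, Dnmt3a against itself across strands gave 0.27 and 0.23, and Tet1 and Tet2 against itself 0.15 and 0.11. Low values of r there describe differences between clusters, not the mean change. Each knockdown against itself across strands gave 0.96 for Dnmt1, 0.77 for Dnmt3a, 0.66 for the double, 0.37 for Tet1 and Tet2 and 0.31 for Dnmt3b. Across single cytosines the covariance of Dnmt3a and the double was 39.3 squared points against 14.4 in the simulation. For Tet1 and Tet2 against Dnmt3b it was 15.3 against 14.5, but the simulated noise was taken from the difference between those libraries, so a real difference between them would raise the simulated value. Of 42 clusters higher for Tet1 and Tet2 and 13 higher for Dnmt3b, 4 were shared, where lists independent within each class would share 0.20. Those lists, too, were made against the same control library. Splitting by strand separates the reads, but the control culture itself remained shared by all pairs.

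On the X chromosome the differences had the same signs as on the autosomes. Over 6850 cytosines, control read 27.8%, Dnmt1 6.34%, Dnmt3a 24.5%, Dnmt3b 28.2%, the double knockdown 25.3% and Tet1 and Tet2 28.9%.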

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

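Sequence outside the autosomes was not part of the main comparisons, and 3 values there lay above control by more than the SD over autosomes. All 3 were smaller than the autosomal gains of the same libraries, 1.40 points for Tet1 and Tet2 and 0.446 for Dnmt3b. On the X chromosome (6850 cytosines) the Tet1 and Tet2 library was 1.01 points above control (28.9% against 27.8%). The Dnmt3b library was 0.365 points above control there. On unplaced sequence (542 cytosines) the Dnmt3b library was 0.327 points above control (49.6% against 49.3%). Values below control were not picked out by this comparison, which was chosen after the data were seen. Among them, the Tet1 and Tet2 library differed from control by -0.252 points on unplaced sequence, opposite in sign to the autosomes. On the 111 cytosines of the Y chromosome without a fixed position it differed by -1.85 points and Dnmt3b by -1.49 points, also opposite to the autosomes. On the 31 placed cytosines of the Y chromosome these differences were -4.69 and -2.28 points. None of these differences was tested.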

How the results depend on the processing

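No mean difference reversed its sign under any alternative run. For counts a reversal was not defined, so they could only stay or move. Of 181 alternative values, 85 stayed within the spread over autosomes or within 1.5 times the count. Strands merged, sex chromosomes included, and each strand alone moved nothing that far, but merging strands and adding sex chromosomes could move little. In control 13488 CpGs had both strands listed, among 574461 autosomal cytosines with a level. The X chromosome added 6850 cytosines to the 369208, and the 2 strands together make up the main set. Coverage minimums, an upper limit on coverage, pooled reads, Fisher thresholds, promoter windows and gene lists were not run, for want of counts and mm9 gene positions. With 1 library per group no replicate can be left out. No paired analysis was possible because each group has 1 library. Strand-wise values, both strands past 10 points, classes set on other libraries and the set without Dnmt1 were chosen after seeing the data. Depth is unknown. Other thresholds of size change counts by construction. For other sets of cytosines, which moved mean differences and counts, the cause was not tested.

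Over cytosines shared with control alone, the mean difference was -4.71 points for Dnmt3a and -3.24 for the double knockdown. Over those listed in the 5 libraries other than Dnmt1, it was -4.51 and -3.25. Over the libraries compared, the double differed by 1.27 points from Dnmt3a, -3.73 from Dnmt3b and 0.786 from the sum. At a median level of at least 50% these were 3.06, -6.47 and 2.55.

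With classes set on the Dnmt3b and the Tet1 and Tet2 libraries, low, intermediate and high cytosines differed from control by -0.90, -43.5 and -68.0 points for Dnmt1. For Dnmt3a low and high cytosines differed by -0.713 and -7.38 points, and for the double by -0.662 and -4.80. Lower clusters were then 1 low and 102 high for Dnmt3a and 1 low and 23 high for the double. With classes set on Dnmt3b alone, the Tet1 and Tet2 differences were 0.476, 5.61 and 1.49 points.

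Among cytosines listed in all 6 libraries, the counts lower and higher were 1321 and 5655 for Tet1 and Tet2, 21672 and 306 for Dnmt3a, 1712 and 3095 for Dnmt3b and 12721 and 470 for the double, with 30 higher for Dnmt1. At 10 points they were 18511 and 48352, 106547 and 7477, 25879 and 35392, and 72942 and 9665, with 288 higher for Dnmt1. At 30 points they were 1139 and 3483, 13470 and 355, 1616 and 2377, and 6982 and 501, with 9 higher for Dnmt1.

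Clusters lower and higher at 10 points were 48 and 675 for Tet1 and Tet2, 3165 and 2 for Dnmt3a, 92 and 312 for Dnmt3b and 1983 and 8 for the double. At 30 points they were 2 and 6, 85 and 0, 0 and 1, and 20 and 0. With at least 3 cytosines they were 22 and 231, 2224 and 2, 41 and 96, and 914 and 5, with 15518 lower for Dnmt1. With at least 10 they were 0 and 2, 71 and 0, 0 and 0, and 21 and 0, with 464 lower for Dnmt1. Gaps of 50 bp gave 3205 lower for Dnmt1, and gaps of 300 bp gave 1 lower for Tet1 and Tet2 and 3 lower for Dnmt3b. Without the Dnmt1 library, 79 were higher for Tet1 and Tet2, 9 lower and 37 higher for Dnmt3b and 448 lower for the double. Of the 12251 clusters with at least 3 cytosines on each strand, counted with both strands past 10 points, 1 was lower and 85 higher for Tet1 and Tet2, 1803 lower for Dnmt1, 10 lower and 40 higher for Dnmt3b and 0 higher for the double.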

Other observations

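All tests in this part were chosen after the results they bear on were seen, except the correlations within intermediate clusters and across the 16 flanking contexts. The methylation left after Dnmt1 knockdown was uneven along the genome. Of 3693 clusters with a mean of at least 60% in the other 5 libraries, the median kept 22.0% of that level, with quartiles of 16.9% and 27.8%. A group of 101 clusters kept at least 50%. A cluster on chromosome 3 (54615277 to 54615318, 8 cytosines) read 78.8% after Dnmt1 knockdown and 70.4% in control, and a cluster on chromosome 6 (65211180 to 65211223) read 74.8% against 75.2%. Levels also differed with the neighbouring bases. At high cytosines outside CCGG, the Dnmt1 library read 24.7% ± 1.4 (SD over autosomes) at CpGs followed by C and 20.3% ± 1.4 at those followed by G, while control read 90.9% and 90.3%. CpGs preceded by G read 19.5% ± 1.3 and those preceded by C 24.6% ± 1.5. Leaving out CCGG removes only sites preceded by C and followed by G, so these groups also differ in their other base. CCGG itself read 20.7% ± 0.6 over 31435 cytosines, against 22.1% at ACGG, 21.2% at TCGG and 18.5% at GCGG.

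A run of 4 neighbouring cytosines with the same contexts, strands and spacings recurred in another cluster for 41 of the 101 (40.6%). Among the 3592 that kept less it recurred for 4.20%, a ratio of 9.66. Clusters sharing a run are not independent, and the ratio counts each of them. In 33 of the 3693 clusters the run was found in at least 10 clusters, and 14 of these 33 are among the 41. The run of the chromosome 6 cluster was found in 37 clusters. The clusters with a recurring run kept a median of 29.4%, the others 21.8%. Incomplete bisulfite conversion of the library is argued against, since its low cytosines read 0.40%; resistance of particular sequences to conversion stays open. A candidate explanation is multi-copy sequence, through reads placed on the wrong copy or through elements that hold methylation with less DNMT1, and these tests do not separate them. It leaves much open: the chromosome 3 cluster has no recurring run, and of the 192 clusters with a recurring run 41 (21.4%) kept at least 50%, so most lost most of their methylation.

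The Dnmt1 library left out methylated cytosines more often than unmethylated ones (34.1% of high against 10.9% of low, a ratio of 3.13). Lower depth stays open: the double knockdown library, second lowest in listed cytosines, had a ratio of 2.86, but the Tet1 and Tet2 library, which listed the most, had 1.34 against 0.771 in control. Drop-out of reads through loss of methylation stays open too. The Dnmt3a library had a ratio of 0.705, but its change of -4.02 points is small beside the -20.3 points of the Dnmt1 library. Depth itself is unknown, and no biological explanation was tested.

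The double knockdown kept more methylation than Dnmt3a alone. The choice of cytosines is argued against, since the difference was at least 1.06 points in each of 4 other sets, the strands among them. Incomplete conversion of the double library is argued against, since low cytosines differed by 0.0972 points and intermediate ones by 4.27. Weaker depletion of Dnmt3a when 2 genes are targeted may account for it, and within intermediate clusters the 2 knockdowns correlated across strands at 0.158. No transcript or protein level was used here, and a difference between single cultures cannot be told apart from it.

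One hypothesis was that Dnmt3a sets which contexts keep methylation after Dnmt1 knockdown. Contexts that kept more would then lose more after Dnmt3a knockdown, but the correlation across 16 contexts was -0.195, which leaves this undecided. The level before knockdown is argued against as the source of the context difference, with a ratio of highest to lowest context of 1.02 in control and 1.47 after Dnmt1 knockdown. A second hypothesis was that gains after Tet1 and Tet2 knockdown follow losses after Dnmt3a knockdown only through shared methylation class. Within low clusters, 10637 of 12251, the correlation across strands was -0.411, which argues against class alone there; differences in level within the low class were not separated. Within intermediate clusters it was -0.114, too close to the bound of -0.1 to decide, and within high clusters -0.105.

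After Dnmt1 knockdown 436 of 436054 autosomal cytosines still read at least 90%. Their median in the other libraries was 100%, and 379 were at 95% or more there.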
